A study of Mus musculus with 6 samples.

How the data were processed

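Messenger RNA was sequenced from primary keratinocytes, the main cell type of the epidermis, taken from the skin of newborn wild-type C57BL/6 mice. Per the labels, the cells were cultured for 2 days and then left untreated or given recombinant IL-33, a cytokine of the IL-1 family, for 12 h. The dose of IL-33 is not given in the sources used here. Each group had 3 libraries, numbered 1 to 3 in the labels. No label says whether the libraries of a group came from separate cultures, litters or animals, so the p-values measure only the spread between these libraries, which may be technical.

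The submitters' processing notes name FastQC 0.11.7, HISAT2 2.1.0, StringTie 1.3.4d, DESeq2 1.18.1 and the genome build mm10, without saying which tool made which table. The annotation release is not given in the sources used here. The deposited tables hold estimated counts and FPKM for each gene and each transcript. The deposited FPKM values are fragments per kilobase of feature scaled to sequencing depth, per the file headers. The deposited estimated counts are whole numbers, so no rounding was needed, but the values show that they are not raw read counts. In each library 99.98% to 99.99% of the abundant transcripts had a count proportional, within 1%, to their FPKM times their exon length. Low values piled up at multiples of 4. Before rounding, rebuilt from FPKM and exon length, values within 0.125 of 4 were found for 1382 transcripts in untreated replicate 1, against 404 for 3 and 317 for 5. The count was 790 at 8, against 264 at 7 and 254 at 9. A smaller pile of 771 lay at 2, while 6 had 402, so the scale is an estimate. A value of 4 deposited counts was taken as about 1 sequenced fragment. The totals per library ran from 34188173 to 45266298 deposited counts, which is 8547043 to 11316574 fragments on that scale. Floors and the counting limit of a ratio of fragments cover counting error only. Intervals of log2 fold changes come from the fit of the main test and include the spread between libraries. The floor used was 3 fragments, or 12 deposited counts, per library, which was 0.265 to 0.352 CPM (the deposited count scaled to the library total). All 37 mitochondrial genes were listed at 0 in every library, so no mitochondrial share could be used as a sign of RNA quality.

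The gene table held 52550 versioned Ensembl identifiers, of which 52403 were matched to a symbol. Positions are those of GENCODE release M21 on GRCm38, the assembly also called mm10, and 97.16% of the deposited transcript identifiers are in that release with the same version. It may not be the release the authors used.

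The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited estimated counts, with TMM scaling, a robust fit and the filterByExpr filter at its minimum count of 10. It compared the 3 IL-33 libraries with the 3 untreated libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are IL-33 minus untreated. Standard errors (SE) are on the log2 scale and intervals are at 95%. CPM values are TMM-scaled means with the standard deviation (SD) over 3 libraries. The same test was run on the transcript table.

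A set of 29 gene lists was fixed before the data were examined, and the 26 with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Each list was also tested with an estimated correlation and with fry, which asks whether the genes of a list move, on balance, one way. Every p-value of a list was adjusted over the 26 lists. For single members, p-values were adjusted over all genes and, separately, adjusted over the list alone.

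The genes named in the text were chosen by a rule fixed before the data were examined. Among genes with adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between groups, the rule took the 10 highest and the 10 lowest log2 fold changes. Where fewer than 5 passed in a direction, it took the 5 with the smallest p in that direction. It added up to 4 members of each list with the smallest p, and Il1rl1, Il1rap and Il33. Predicted genes were skipped, and any gene named outside the rule is said to have been chosen after its values were seen.

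The alternatives were other scaling factors, DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts, other thresholds, the replicate number as a block, each library left out in turn, and limma on log2(FPKM + 0.1) and log2(FPKM + 1). Deposited counts divided by 4, with edgeR and with DESeq2, and the NF-kB list without the chemokines it shares with another list, were added after the data had been seen. All pairs of libraries differed by more than sampling noise, with a median chi-square of 1.98 to 2.91 times its sampling value over 12161 genes, so no library was counted as a copy of another.

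The test was run on simulated counts with the means and spread of these libraries, with 50 of 15519 genes changed at each of 4 sizes. For the simulated IL-33 comparison it recovered 0% of genes changed 1.25-fold, 50% at 1.5-fold, 84% at 2-fold and 98% at 4-fold. There were 4 false calls, 3.33% of all calls. Most differences under 1.5-fold are therefore below what the test can call in 3 against 3 libraries of this depth. The simulated changes were placed in genes with a mean log2 CPM of at least 1, so the shares do not cover lower genes. They also outnumbered the 11 calls made on the real data. That loosens the Benjamini-Hochberg cutoff, so the shares may overstate recovery in the real comparison.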

Results

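Transcript levels were measured by RNA sequencing in mouse primary keratinocytes after 2 days of culture, without treatment or after 12 h with recombinant IL-33. There were 3 libraries per group. The untreated libraries held 44692876, 41456441 and 45266298 deposited estimated counts, and the IL-33 libraries 43860488, 34188173 and 44255925. IL-33 replicate 2 was the shallowest library. Keratins of basal cells were far above those of suprabasal cells. The basal keratins Krt5 and Krt14 stood at 18034 ± 242 and 14350 ± 392 CPM in untreated cells (SD, n = 3), and the suprabasal keratins Krt1 and Krt10 at 1.45 ± 0.544 and 2.39 ± 0.738 CPM. These 4 keratins were chosen after their values were seen.

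The design asks which transcripts of keratinocytes respond to IL-33 within 12 h. Between the groups, 11 of 15778 tested genes changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 7 of them higher and 4 lower with IL-33. Golim4, which encodes a Golgi membrane protein, rose 1.55-fold, from 228 ± 4.07 to 354 ± 11.8 CPM (SD, n = 3 per group; edgeR adjusted p = 6.06e-04). Nfya, a subunit of the CCAAT-binding factor NF-Y, rose 1.89-fold, and Tfdp2, a dimerization partner of E2F transcription factors, rose 2.50-fold. Dctd, the deaminase that makes dUMP from dCMP, fell from 49.97 ± 2.15 to 28.1 ± 0.233 CPM. In each of the 11 genes all 3 IL-33 libraries lay on one side of all 3 untreated libraries, an order that 13.65% of all tested genes showed and that chance gives to 10%.

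Nfya (ENSMUSG00000023994.13, chromosome 17, 48386885 to 48409906) went from 37.5 ± 1.48 to 70.7 ± 4.08 CPM, a log2 fold change of 0.92 with an SE of 0.069 (edgeR adjusted p = 0.00128). Tfdp2 (ENSMUSG00000032411.15, chromosome 9, 96196275 to 96323646) went from 10.1 ± 1.31 to 25.4 ± 1.42 CPM (log2 fold change 1.32, SE 0.12, edgeR adjusted p = 0.00231). Golim4 (ENSMUSG00000034109.15, chromosome 3, 75875084 to 75956949) had a log2 fold change of 0.63 with an SE of 0.041. For Dctd (ENSMUSG00000031562.15, chromosome 8, 48099092 to 48153233) it was -0.83 with an SE of 0.068 (edgeR adjusted p = 0.00138). Mark4, a kinase of microtubule-associated proteins, rose from 58.2 ± 1.28 to 85.1 ± 5.76 CPM, and Capns1, the small subunit of calpain proteases, from 313 ± 22.9 to 449 ± 28.1 CPM, with edgeR adjusted p of 0.0207 and 0.0245. Fam172a fell from 34.4 ± 0.931 to 17.6 ± 3.02 CPM and the zinc finger gene Zfp800 from 30.4 ± 2.08 to 18.7 ± 1.21 CPM, with edgeR adjusted p of 0.0237 and 0.0363. Rpl24, a protein of the large ribosomal subunit, fell from 593 ± 34.7 to 451 ± 12.0 CPM (edgeR adjusted p = 0.0207).

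The predicted genes Gm21969 and 2610001J05Rik also rose, and both were chosen after their values were seen. Gm21969 (chromosome 4, 139603186 to 139662691) had 11, 11 and 10 deposited counts in the untreated libraries and 138, 196 and 178 in the IL-33 libraries. The untreated values lie below the floor of 12 deposited counts, so no exact ratio is given. As fragments they are 8 against 128 (edgeR adjusted p = 0.00138), and the lower 95% counting limit of the depth-scaled ratio is 8.47. 2610001J05Rik went from 18.5 ± 0.954 to 36.9 ± 4.01 CPM (edgeR adjusted p = 0.0053).

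**Figure D1:**
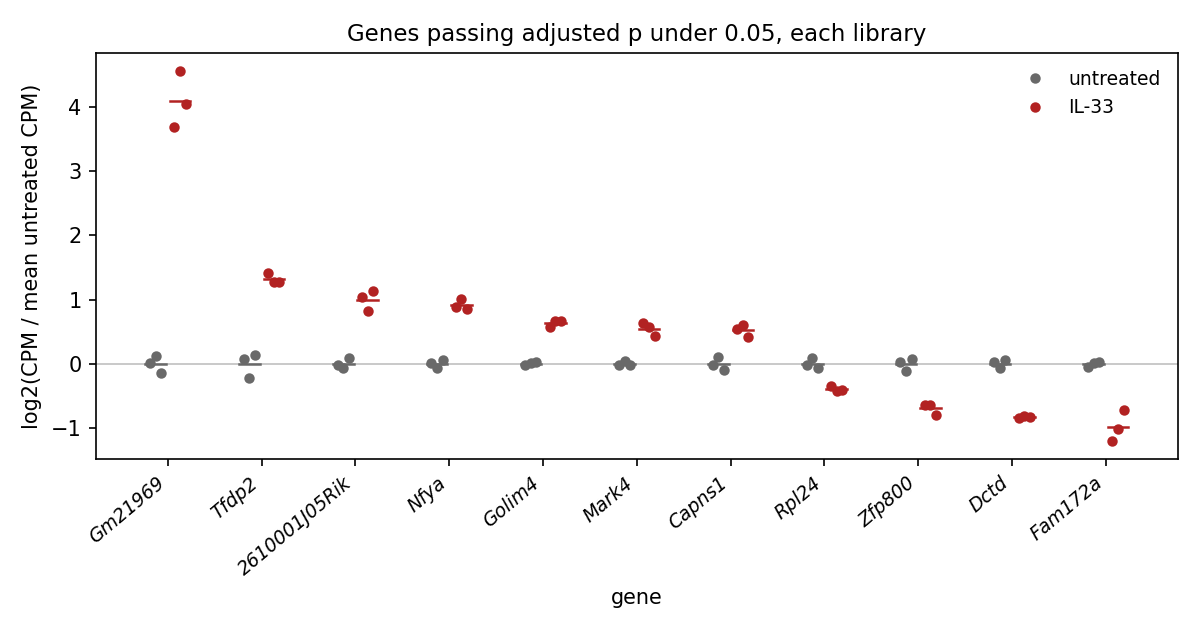
Level of each of the 11 genes with an edgeR adjusted p under 0.05 in every library, as log2 of CPM over the mean untreated CPM, with 3 untreated libraries in grey and 3 IL-33 libraries in red; short lines are group means. The groups do not overlap in any of the 11 genes, and most group differences lie within about 1 log2 unit, apart from Tfdp2 at 1.32 and Gm21969, whose untreated values lie below the floor.

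Of the 11 called genes, 7 overlap another annotated gene, so their counts are uncertain, and Rpl24 is the one whose partner moved the other way by a comparable amount. Mean scaled counts of Rpl24 fell by 6024.5 while those of Gm28037, which overlaps it on the same strand of chromosome 16 and was chosen after its values were seen, were higher by 3414. Gm28037 went from 50.04 ± 15.0 to 131 ± 24.9 CPM and did not pass (edgeR adjusted p = 0.575). Golim4, Nfya, Tfdp2, Dctd, Gm21969 and 2610001J05Rik kept their calls whichever library was left out. With limma on FPKM, Tfdp2 was not called at any of 3 settings (adjusted p = 0.161, 0.143 and 0.27; range from 1.53e-17 over all settings), with a log2 fold change of 0.67 on log2(FPKM + 1). Nor was 2610001J05Rik (adjusted p from 0.0565 to 0.121; range from 7.24e-14). Gm21969 was tested with limma on FPKM only where every gene with an FPKM above 0 was kept. It was not called there (adjusted p = 0.121, in a range from 9.09e-18 over the 17 settings that tested it). Mark4 lost its call without untreated replicates 1, 2 and 3 (edgeR adjusted p = 0.102, 0.0628 and 0.0796) and without IL-33 replicates 1 and 2 (0.0602 and 0.0898), in a range of 1.03e-08 to 0.25 over all settings. Zfp800 lost it without the same 5 libraries (edgeR adjusted p = 0.132, 0.0557, 0.111, 0.063 and 0.0978; range 1.64e-06 to 0.274). Capns1 lost it without untreated replicates 1 and 3 and IL-33 replicates 1 and 2 (edgeR adjusted p = 0.132, 0.0664, 0.108 and 0.0898; range 3.92e-10 to 0.274). Fam172a lost it without untreated replicates 1, 2 and 3 and IL-33 replicate 2 (edgeR adjusted p = 0.079, 0.0938, 0.0919 and 0.0971; range 9.39e-10 to 0.299). Rpl24 lost it without untreated replicate 1 and IL-33 replicate 2 (edgeR adjusted p = 0.0762 and 0.0971; range 1.49e-08 to 0.239). With the replicate number as a block, Mark4, Rpl24 and Zfp800 lost their calls (edgeR adjusted p = 0.0733, 0.0733 and 0.166). The count of called genes was 90 without IL-33 replicate 3, 20 without IL-33 replicate 1 and 18 without untreated replicate 3, and DESeq2 called 71 genes, all 11 among them.

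RNA of both chains of the IL-33 receptor was found in both groups, and neither gene passed the test. Receptor protein was not measured, and which form of ST2 each transcript encodes was not examined. Il1rl1, which encodes the ligand-binding chain ST2, stood at 72.4 ± 1.42 CPM untreated and 71.4 ± 2.85 CPM with IL-33 (SD, n = 3 per group; log2 fold change -0.02, 95% interval -0.15 to 0.11, edgeR adjusted p = 0.967). Il1rap, the shared co-receptor chain, stood at 36.7 ± 3.41 and 32.7 ± 0.767 CPM, and Il33 itself at 8.26 ± 1.40 and 9.91 ± 0.959 CPM. Most of the Il1rl1 signal was assigned to the transcript ENSMUST00000173514.7, at 67.9 ± 1.95 and 63.2 ± 4.21 CPM, and ENSMUST00000053043.7 held 3.41 ± 1.23 and 3.32 ± 1.31 CPM. ENSMUST00000097772.9 stood at 1.32 ± 0.769 and 4.94 ± 3.51 CPM (edgeR adjusted p = 1), and ENSMUST00000174335.7 at 0.306 ± 0.0458 CPM, near the floor, and at 0 in all 3 IL-33 libraries (edgeR adjusted p = 0.596). Of the 13 genes of the receptor and its signalling, 8 had a log2 fold change above 0 and none passed, over all genes or adjusted over the list alone (0 also at an unadjusted p under 0.05; camera adjusted p = 0.437). The adaptor Myd88 stood at 25.7 ± 0.296 and 29.5 ± 4.25 CPM and the kinase Irak1 at 85.7 ± 6.66 and 94.1 ± 1.75 CPM.

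Across the fixed gene lists, no member passed over all 15778 genes with edgeR, while 80 of 519 list genes had an unadjusted p under 0.05. limma-voom called 0 of them. DESeq2 called 8: Itga3, Krt16, Cenpe, Mki67, Sprr2a2, Sprr2a1, Ccl2 and Ccl20, with adjusted p from 6.57e-05 for Itga3 to 0.0487 for Ccl20, and on counts divided by 4 it called 2, Itga3 and Krt16. Adjusted over the list alone, 18 genes passed, of which 3, Krt16 and Itga3 among them, did so whichever library was left out. Camera with its preset correlation called 6 of the 26 tested lists, all higher with IL-33, and none of them held with an estimated correlation or in fry after adjustment.

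Chemokines rose as a list by camera with its preset correlation (adjusted p = 0.0297), and not with an estimated correlation (adjusted p = 0.458, the top of a range from 0.00299 over its settings) or in fry. Ccl20, which attracts cells bearing the receptor CCR6, stood at 2.19 ± 0.351 CPM untreated and 4.88 ± 1.49 CPM with IL-33 (SD, n = 3 per group), and the monocyte attractants Ccl2 and Ccl7 at 7.17 ± 1.06 against 11.6 ± 1.16 and at 0.649 ± 0.191 against 1.63 ± 0.474 CPM. Of 14 tested chemokines 12 had a log2 fold change above 0, with a median of 0.16. That median depended on the libraries used: 0.34 without untreated replicate 1, 0.32 without IL-33 replicate 2, and 0.10 without untreated replicate 2. With all libraries but counts divided by 4, where 12 chemokines were tested, it was 0.06. None passed over all genes with edgeR (Ccl2 adjusted p = 0.319), and 3 did adjusted over the list alone, Ccl2 and Ccl20 at 0.0093 each and Ccl7 at 0.0335. Camera's call for chemokines ended without untreated replicates 2 and 3 (adjusted p = 0.126 and 0.092) and without IL-33 replicates 1 and 3 (0.122 and 0.0682). Ccl2 and Ccl20 missed the threshold over the list alone without untreated replicate 3 (adjusted p = 0.054 each). Ccl7 missed it without untreated replicates 2 and 3 and IL-33 replicates 1 and 2 (adjusted p = 0.115, 0.0709, 0.148 and 0.0964). Fibroblast markers, from cells that also make these chemokines, summed to 194 ± 18.9 CPM untreated and 189 ± 22.5 CPM with IL-33.

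NF-kB target genes rose as a list with the preset correlation, with 20 of 24 members above 0 and a median log2 fold change of 0.08 (camera adjusted p = 0.0342). With the estimated correlation of this list, 0.19 against the preset 0.01, the camera adjusted p was 0.669. That was the top of a range from 8.87e-05 over the list's settings. None passed over all genes with edgeR, 2 had an unadjusted p under 0.05, and Ccl20 passed adjusted over the list alone (0.0319), though without 5 of the 6 libraries it did not, with adjusted p of 0.0905, 0.111 and 0.148 without untreated replicates 1, 2 and 3 and 0.0773 and 0.157 without IL-33 replicates 1 and 3. Birc3, an inhibitor of apoptosis, stood at 12.3 ± 1.88 and 15.8 ± 1.22 CPM, the chemokine Cxcl2 at 16.1 ± 1.78 and 19.6 ± 3.72 CPM, and Ier3, an early response gene, went the other way at 137 ± 8.12 and 122 ± 14.3 CPM. The call for NF-kB targets ended without untreated replicates 2 and 3 (camera adjusted p = 0.244 and 0.0956), without IL-33 replicates 1 and 3 (0.314 and 0.216), and without the members shared with the chemokine list (0.0846). The median was 0.13 without untreated replicate 1. Interferon-stimulated genes had a median log2 fold change of 0.10 with 20 of 28 above 0 (camera adjusted p = 0.0444; adjusted p = 0.458 with an estimated correlation, the top of a range from 0.02 over its settings). The GTPase gene Igtp stood at 1.75 ± 0.294 and 2.92 ± 0.549 CPM and the transcription factor Irf1 at 6.84 ± 1.36 and 9.17 ± 0.865 CPM, and 0 of the 28 passed over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05. The interferon call ended without untreated replicates 1 and 3 (camera adjusted p = 0.0508 and 0.0956) and without IL-33 replicates 1 and 3 (0.218 and 0.0954). It also ended with the replicate number as a block (camera adjusted p = 0.0755). The interferon list's median was 0.17, 0.18 and 0.16 without untreated replicates 1 and 2 and IL-33 replicate 3.

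Genes of terminal differentiation rose as a list by camera with its preset correlation. Of 39 tested, 28 had a log2 fold change above 0, with a median of 0.13 (camera adjusted p = 0.00599; adjusted p = 0.458 with an estimated correlation, the top of a range from 0.00278 over its settings). The cornified envelope genes Sprr2a2 and Sprr2a1 stood at 67.4 ± 2.47 against 83.2 ± 3.08 CPM and at 57.3 ± 2.22 against 71.0 ± 3.09 CPM (SD, n = 3 per group). They passed adjusted over the list alone (0.0135 each), but they are near-identical neighbours with overlapping positions on chromosome 3, so their separate counts are uncertain. They missed that threshold without untreated replicates 1 and 2 (0.0696 and 0.0893) and without IL-33 replicate 2 (0.0769). Krt80, a keratin of differentiating cells, stood at 46.8 ± 2.21 and 54.4 ± 0.914 CPM and the envelope protein gene Evpl at 66.0 ± 2.22 and 75.4 ± 4.56 CPM. Ivl, another envelope precursor, went the other way at 5.72 ± 0.527 and 4.07 ± 1.00 CPM, and was chosen after its values were seen. The list's call ended without untreated replicate 1 (camera adjusted p = 0.0682), and its median was 0.08 without IL-33 replicate 1.

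Genes of basal keratinocytes and the basement membrane did not pass as a list (22 genes, 7 above 0, median log2 fold change -0.07, camera adjusted p = 0.157). Their summed level was 44369 ± 513 CPM untreated and 44904 ± 1553 CPM with IL-33. Most of that sum came from Krt5, at 18034 and 18995 CPM, and Krt14, at 14350 and 14645 CPM. The sum therefore says little about the other members, and 15 of the 22 had a log2 fold change below 0. Itga3 stood at 1531 ± 34.5 CPM untreated and 1229 ± 80.4 CPM with IL-33 (SD, n = 3 per group; log2 fold change -0.32, SE 0.048), which missed the threshold over all genes (edgeR adjusted p = 0.0768) but passed it without IL-33 replicates 1 and 3 (0.0273 and 0.0261), in a range of 6.57e-05 to 0.488 over all settings. Lama3 stood at 599 ± 15.6 and 545 ± 4.64 CPM and Itgb4 at 1120 ± 10.0 and 954 ± 90.2 CPM. None of the 22 passed over all genes, 12 had an unadjusted p under 0.05, and 6 passed adjusted over the list alone. Among these were Itga3, Lama3, Itgb4 and Lama5, all lower, and Dlk2, which was higher; Lama5 and Dlk2 were chosen after their values were seen. Adjusted over the list alone, Lama3 lost its pass without untreated replicates 1 and 3 (0.0851 and 0.0675), Itgb4 without untreated replicates 1, 2 and 3 (0.0851, 0.0712 and 0.0698), Dlk2 without untreated replicates 1 and 3 and IL-33 replicate 2 (0.122, 0.0698 and 0.0961), and Lama5 without those 3 libraries and IL-33 replicate 3 (0.122, 0.0819, 0.0961 and 0.0787).

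Krt16, a keratin of wounded and hyperproliferative epidermis, stood at 297 ± 6.03 CPM untreated and 360 ± 11.9 CPM with IL-33 (SD, n = 3 per group; log2 fold change 0.28, SE 0.041). It missed the threshold over all genes (edgeR adjusted p = 0.0666), passed it without IL-33 replicate 3 (0.0334; range 0.000195 to 0.274 over all settings), and passed adjusted over the list alone (0.000811). Other genes of the same list went the other way: the hyaluronan receptor Cd44 stood at 549 ± 23.5 and 463 ± 37.7 CPM, the matrix protein gene Tnc at 389 ± 10.5 and 326 ± 30.4 CPM and the protease inhibitor Serpinb2 at 350 ± 32.4 and 299 ± 23.7 CPM. Cd44 and Tnc passed adjusted over the list alone (0.016 each) and lost it without untreated replicates 1 and 2 (0.0712 and 0.0676 for each) and IL-33 replicate 2 (0.0574 and 0.0701). The 16 genes had a median log2 fold change of -0.06 (camera adjusted p = 0.522), with 7 above 0 and 9 below. Among the 7 were the keratins Krt17, Krt6b and Krt6a, with log2 fold changes of 0.10, 0.08 and 0.05. These 3 were chosen after their values were seen and did not pass adjusted over the list alone. Genes of hair follicle lineages, 7 tested and 6 above 0, rose as a list with the preset correlation (camera adjusted p = 0.0444), with a median of 0.17. With an estimated correlation the camera adjusted p was 0.458, the top of a range from 0.0141 over the list's settings. Of the 7 genes, 0 passed over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. Among them Msx2, a homeobox gene, stood at 10.95 ± 1.37 and 13.7 ± 1.87 CPM. The hair follicle call ended without untreated replicates 1, 2 and 3 (camera adjusted p = 0.0563, 0.132 and 0.0956) and without IL-33 replicates 2 and 3 (0.108 and 0.0954).

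Cell cycle genes rose as a list by a small amount, with 31 of 38 above 0 and a median log2 fold change of 0.07 (camera adjusted p = 0.00275; adjusted p = 0.632 with an estimated correlation, the top of a range from 8.87e-05 over its settings). The proliferation marker Mki67 stood at 205 ± 16.2 CPM untreated and 246 ± 2.39 CPM with IL-33, the kinetochore motor Cenpe at 46.0 ± 4.21 and 60.0 ± 1.77 CPM, and the spindle factor Tpx2 at 161 ± 7.08 and 184 ± 5.51 CPM (SD, n = 3 per group). None of the 38 passed over all genes with edgeR, 10 had an unadjusted p under 0.05, and Cenpe, Mki67 and Tpx2 passed adjusted over the list alone (0.0192, 0.0192 and 0.0391). Cenpe and Mki67 lost that pass without IL-33 replicates 1 and 2 (0.0561 and 0.0812 for each), and Tpx2 without untreated replicates 2 and 3 and IL-33 replicates 1 and 2 (0.124, 0.179, 0.0561 and 0.0985). The list's call ended without IL-33 replicate 3 (camera adjusted p = 0.216), where its median was 0.04.

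**Figure D2:**
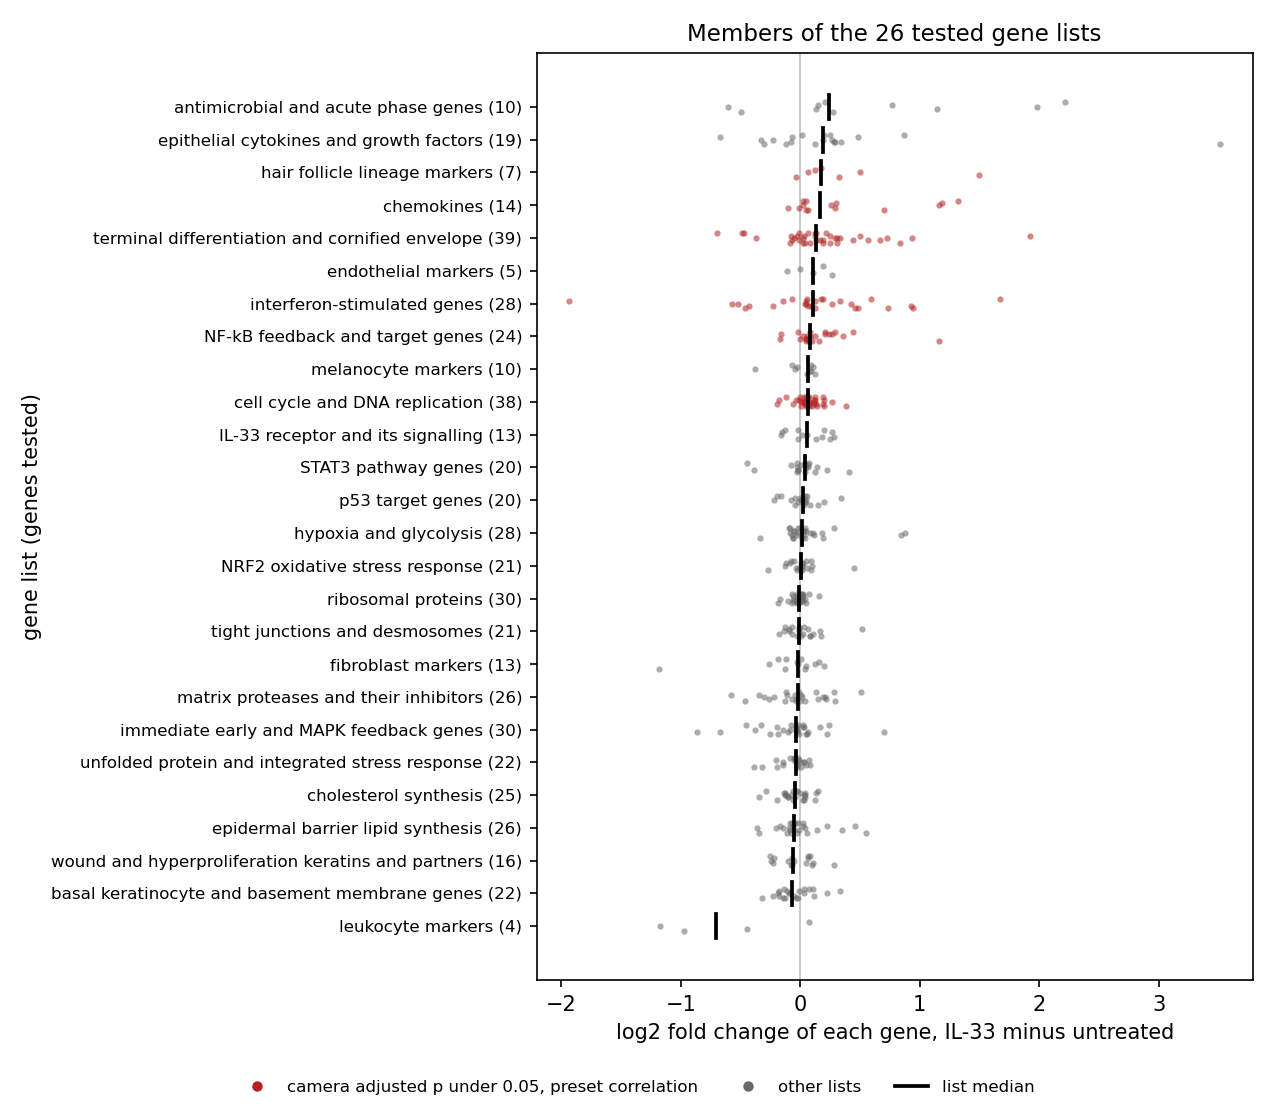
Log2 fold change (IL-33 minus untreated) of each tested member of the 26 gene lists, ordered by list median, with the black line at the median and lists called by camera with the preset correlation in red. Medians of the 6 called lists lie between 0.07 and 0.17, and members of most lists fall on both sides of 0.

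Cytokine, antimicrobial and MAPK feedback genes did not pass as lists. Defb1, an epithelial defensin, stood at 60.8 ± 3.10 and 73.4 ± 1.67 CPM and passed adjusted over its list alone (0.0148), but not without untreated replicates 2 and 3 (0.0952 and 0.0662) or IL-33 replicates 1 and 2 (0.0614 and 0.0728). The IL-36 cytokine gene Il1f6 had 0, 0 and 9 deposited counts in the untreated libraries and 35, 23 and 41 in the IL-33 libraries, where 4 counts are about 1 fragment (edgeR adjusted p = 0.622). Il1f9, another IL-36 cytokine gene, stood at 1.55 ± 0.765 and 2.82 ± 0.538 CPM. Antimicrobial genes had a median log2 fold change of 0.24 (10 genes, camera adjusted p = 0.138) and epithelial cytokines and growth factors 0.19 (19 genes, camera adjusted p = 0.522). Immediate early and MAPK feedback genes had a median of -0.03 (30 genes, camera adjusted p = 0.0634), among them the ERK phosphatases Dusp6 at 102 ± 3.77 and 78.3 ± 12.5 CPM and Dusp5 at 61.4 ± 1.23 and 51.6 ± 1.73 CPM, and the EGF receptor ligand Hbegf at 23.5 ± 2.84 and 18.7 ± 1.32 CPM. None of the members of these 3 lists passed over all genes with edgeR, with 3, 4 and 8 at an unadjusted p under 0.05.

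Lists of metabolism, stress and structure showed no call. Median log2 fold changes were -0.04 for cholesterol synthesis (camera adjusted p = 0.292), -0.05 for barrier lipid synthesis (0.255), 0.02 for hypoxia and glycolysis (0.681), -0.03 for the unfolded protein and integrated stress response (0.137), 0.03 for p53 targets (0.675), 0.04 for STAT3 pathway genes (0.437) and -0.02 for matrix proteases (0.759). For the NRF2 response the median was 0.01 while camera ranked the list lower (0.674), and for tight junctions and desmosomes the median was -0.01 and the mean 0.02 (0.931). The chaperone gene Dnajb9 stood at 21.5 ± 1.43 and 16.4 ± 1.37 CPM. Ribosomal protein genes, fixed as a sign of RNA quality, had a median of -0.01 (camera adjusted p = 0.541).

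Among the lists fixed as markers of other cells, that of hair follicle lineages was called higher (camera adjusted p = 0.0444; adjusted p = 0.458 with an estimated correlation), as were the differentiation and cell cycle lists. Its genes summed to 46.0 ± 1.99 CPM untreated and 51.8 ± 3.01 CPM with IL-33. Markers of melanocytes, endothelial cells, leukocytes and fibroblasts did not pass as lists. The melanocyte genes summed to 1376 ± 29.9 CPM untreated and 1409 ± 64.0 CPM with IL-33 (camera adjusted p = 0.58). Among them were the pigment enzymes Dct, at 313 ± 11.8 and 333 ± 15.3 CPM, and Tyrp1, at 307 ± 12.0 and 325 ± 7.08 CPM. Endothelial markers summed to 37.1 ± 3.06 and 38.6 ± 1.53 CPM (camera adjusted p = 0.58) and leukocyte markers to 10.97 ± 0.645 and 10.9 ± 1.45 CPM (0.501). Fibroblast markers had a median log2 fold change of -0.02 (camera adjusted p = 0.674), with the collagen gene Col1a1 at 7.70 ± 4.31 and 3.38 ± 0.887 CPM. The mast cell and erythroid lists had 1 tested gene each and were not tested as lists. For mast cells it was Kit, at 18.5 ± 1.70 and 17.9 ± 1.98 CPM, while the other 9 of the 10 listed genes were not tested. Kit alone therefore does not show that mast cells were present. For erythroid cells it was Alas2, at 0.254 ± 0.0962 CPM untreated, a mean below the floor, and 0.456 ± 0.244 CPM with IL-33. The mitochondrial mRNAs, which were listed at 0, were not tested as a list either.

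In the transcript table, 12 of 40163 tested transcripts changed, 6 higher and 6 lower (edgeR adjusted p under 0.05), from 11 genes of which Golim4 alone was also called as a gene. The Golim4 transcript ENSMUST00000117242.7 rose with a log2 fold change of 0.67 (SE 0.034, edgeR adjusted p = 0.0113). The others came from genes whose totals did not pass, and all transcripts named here apart from those of Il1rl1 were chosen after their values were seen. The Nsun2 transcript ENSMUST00000176485.7 had 189, 189 and 192 CPM in the untreated libraries and 0 in all 3 IL-33 libraries, while the gene total had a log2 fold change of 0.00 (edgeR adjusted p = 0.997). In Ampd3, ENSMUST00000170374.7 fell from 76.3, 79.9 and 80.9 to 11.8, 11.8 and 12.8 CPM while ENSMUST00000213373.1 rose to 69.2, 75.2 and 72.2 CPM, and the gene total had a log2 fold change of 0.06 (edgeR adjusted p = 0.884). The count of changed transcripts was 6 without untreated replicate 2, 7 without IL-33 replicate 1 and 28 without IL-33 replicate 3. With the replicate number as a block it was 0. Transcripts at 10 CPM or more in all libraries of one group and at 0.5 CPM or less in all of the other numbered 11. Other splits of the 6 libraries into 3 and 3 gave 7 to 15, so such switches were not particular to the IL-33 grouping.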

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

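Counts divided by 4 with edgeR or DESeq2, and the NF-kB list without its shared chemokines, were tests chosen after the data had been seen. The 11 called genes were the same genes with RLE, upper-quartile or no further scaling, with limma-voom, with the stricter filter and with edgeR on counts divided by 4. DESeq2 called 71 genes (32 higher, 39 lower), and 31 (14 higher, 17 lower) on counts divided by 4, with all 11 among them both times. No filter gave 17 genes, 7 of them lower. limma on FPKM gave 4 (3 higher, 1 lower) at each of its 3 settings, of which 3 were among the 11. At adjusted p under 0.01 there were 6 genes, 1 of them lower, and at 2-fold or more 3, with 3 higher and 0 lower. Leaving out 1 library gave 11 to 90 genes (8 to 16 higher, 3 to 74 lower), with the highest counts without IL-33 replicate 3; the cause was not tested. The 6 called lists became 0 with an estimated correlation and 0 with fry (where 2 of them had an unadjusted p under 0.05), and 1 to 6 without 1 library, with 1 without IL-33 replicate 3. The 12 called transcripts became 6 without untreated replicate 2 and 28 without IL-33 replicate 3, the lowest and highest of the 6 fits; the cause was not tested. Whether the replicate numbers pair the samples could not be settled. Correlations of same-numbered libraries were low, at 0.083, 0.076 and 0.01. Yet every library correlated best with its own number, a hint from the data and not from the design. With the number as a block, 8 genes passed (2 lower), all among the 11, and 5 lists and 0 transcripts, and the chemokine median was 0.06. Among genes not called, log2 fold changes without 1 library ran from -0.054 to 0.003 for Il1rl1 and from -0.29 to 0.14 for Krt10, and turned sign without IL-33 replicate 2 and untreated replicate 2. Depth limits low genes: at 8547043 to 11316574 fragments per library, Il1f6 rests on 9 deposited counts untreated and 99 with IL-33, where 4 are about 1 fragment.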

Other observations

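The tests of splits for gene counts, of ERK and YAP target lists, and of fibroblast and leukocyte markers were chosen only after the result they bear on had been seen, as was the threshold for transcripts present in one group alone.

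A list of 26 genes whose transcription follows ERK signalling was drawn up after the results were seen, from knowledge that some members were lower, and shares 15 members with the fixed lists, so it is not independent evidence. Of these genes 18 had a log2 fold change below 0, and at an unadjusted p under 0.05 there were 12 lower and 1 higher (adjusted p = 0.0625 by camera with an estimated correlation). Epha2, a receptor tyrosine kinase, stood at 231 ± 12.1 CPM untreated and 180 ± 12.4 CPM with IL-33 (SD, n = 3 per group; edgeR adjusted p = 0.139; DESeq2 adjusted p = 3.96e-04; called at 4 of 19 other settings), the ETS factor Etv5 at 58.2 ± 1.16 and 49.2 ± 2.42 CPM and Dusp5 at 61.4 ± 1.23 and 51.6 ± 1.73 CPM. Outside the list of 26, Ptgs2, the inducible prostaglandin synthase, stood at 329 ± 13.03 and 265 ± 23.1 CPM (edgeR adjusted p = 0.307, DESeq2 adjusted p = 0.00821). It was chosen after its values were seen. None of the 26 passed over all genes with edgeR.

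Genes changed with IL-33. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 11 genes and the highest other split 12, and 3 of the 10 gave at least 11. The lowest edgeR adjusted p of any gene was 6.06e-04 in the real split. Some other splits gave a lower one, at 5.68e-07, 4.78e-06, 4.45e-05 and 3.87e-04, and the rest a higher one. A small adjusted p of a single gene was therefore not particular to the IL-33 grouping. Reads assigned differently between overlapping genes would put a partner moving the other way beside most called genes, but 1 of the 11 had one, Rpl24. This is argued against for the set, while it stays open for Rpl24 and for Gm21969. Genes overlapping Gm21969 on the same strand were also higher, which a search for opposite moves cannot weigh. A fit without the shallower IL-33 library, replicate 2, also called 11 genes, 6 of them among the 11 (as many as without untreated replicate 1). Those 6 calls therefore did not need that library, and it stays open as a source of the rest. The median absolute log2 fold change of the 11 was 1.009 times its value with that library (0.84 against 0.83). This ratio decides nothing. The 11 were called with that library and their groups do not overlap, so their difference could hardly vanish without it. The IL-33 treatment itself stays open, as no test here separates it from other differences between the groups.

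Differentiation genes higher with IL-33 relative to basal genes. Camera with its preset correlation called the differentiation list (adjusted p = 0.00599; adjusted p = 0.458 with an estimated correlation and 0.276 in fry) and not the basal list (adjusted p = 0.157), and the difference of 0.20 log2 units between their medians was not itself tested. After a correction for gene length and GC content it was 1.193 times its value before (0.26 against 0.21), with camera's unadjusted p at 5.22e-04 for differentiation and 0.0043 for basal genes (4.61e-04 and 0.0606 before), and without IL-33 replicate 2 it was 0.853 times its value (0.17 against 0.20), which argues against both as the whole source. Lower ERK output may accompany the pattern: the median of the ERK genes was -0.18, with an adjusted p = 0.0625 by camera with an estimated correlation, so it stays open. The median of 22 YAP and TEAD target genes was -0.0083 with members on both sides of 0 (adjusted p = 0.729 with an estimated correlation), which decides nothing, and the IL-33 treatment itself stays open.

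Chemokines higher with IL-33. More fibroblasts in the IL-33 cultures would raise fibroblast markers about as much as Ccl2, but the upper quartile of their log2 fold changes was 0.05 (0.046), against 0.35 for a rise of 50% of that of Ccl2 on the log2 scale. More leukocytes stay open, since Ptprc, Tyrobp, Fcer1g, Laptm5 and Cd52 together had 6.75 fragments over the 3 IL-33 libraries and 2.25 over the untreated ones, below a floor of 45 (3 fragments for each gene and library) and too few to decide. A response of the keratinocytes themselves was not tested and stays open.

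For transcripts the real split gave 12 calls and the highest other split 11, and for gene lists 6 and 4. In both, 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Transcripts at 10 CPM or more in all libraries of one group and at 0.5 CPM or less in all of the other numbered 11 in the real split and 7 to 15 in the other splits. At an unadjusted p under 0.05 the real split gave 1063 genes, where 789 would be reached by chance alone with uniform p-values, and the highest other split gave 860. On the first principal component, with 26.1% of the variance, IL-33 replicate 2 stood apart at 52.9 and IL-33 replicate 3, at -6.63, lay beside untreated replicate 3 at -6.11.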
